A study of Homo sapiens with 6 samples.

How the data were processed

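RNA from MDA-MB-231 cells was extracted with TRIzol, and polyadenylated RNA was made into libraries with a VAHTS Universal kit, per the labels' protocols. The series holds 3 control and 3 khellin libraries, and the groups were taken from the sample titles. The deposited table holds raw read counts per gene, made by the authors with fastp, HISAT2 and HTSeq according to the submitters' processing notes. The strand setting, genome build and annotation release were not given in the sources used here. The coordinates of 25335 of 25378 gene identifiers shared with GENCODE release 29 overlapped that release on GRCh38, so this build was inferred by comparison. The table lists 27776 genes, of which 17095 are protein-coding, 10665 are long noncoding and 16 are others. Each listed gene had at least 1 read in total, and 7447 were named only by an Ensembl identifier. The sample titles call the libraries biological replicates, but no source used here says that they came from separate cultures, so p-values of the gene tests measure the spread between these samples.

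CPM, counts scaled to library size, were computed with TMM factors, and genes were kept with edgeR's filterByExpr by group, which left 15865. Differences between groups were tested with edgeR's quasi-likelihood test (robust fit, group only), 2-sided, with Benjamini-Hochberg adjustment and an adjusted p under 0.05. The standard error of a log2 fold change was its absolute value divided by the square root of the F statistic. The biological coefficient of variation was 6.95%. With 28631578 to 30956610 counts per library, 3 counts corresponded to 0.0969 to 0.105 CPM. Library totals and shares were compared with 2-sided exact permutation tests, whose smallest possible p is 0.1. Pairs of libraries of a group were compared by chi-square per degree of freedom over genes with at least 20 reads per pair, which ranged from 1.91 (khellin replicates 1 and 3) to 20.8 (control replicates 1 and 3), so no library was a copy of another.

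The gene lists were written before the data were examined. They cover autophagy machinery, autophagy receptors, lysosome and TFEB targets, the mTORC1 pathway, the integrated stress response, endoplasmic reticulum chaperones, heat shock, NRF2, ferroptosis, p53, apoptosis, hypoxia, glycolysis, cholesterol and fatty acid synthesis, G1/S, mitosis, histones, NF-kB, interferon-stimulated genes, antigen presentation, immediate early genes, the aryl hydrocarbon receptor, TGF-beta, YAP, mesenchymal, epithelial, luminal, fibroblast and endothelial, and blood cell markers, taxane response, ribosomal proteins, ribosome biogenesis, oxidative phosphorylation and mitochondrially encoded genes. Each list with at least 5 tested members was tested with limma's camera on log2 CPM (prior count 2, preset correlation 0.01), adjusted over the lists by Benjamini-Hochberg. Of the 34 lists tested, 18 passed, 11 higher and 7 lower, and 2 passed with an estimated correlation. Members past the test were also counted with edgeR p-values adjusted over the list alone. Some lists share members. Among tested members, 10 for NRF2, 10 for the integrated stress response and 12 for hypoxia stand in other lists.

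The rule for named genes was also fixed before the data were examined. It took DDIT4, the 10 largest rises and the 10 largest falls among called genes with a symbol, a mean of at least 5 CPM and no overlap between groups, the 3 members of each list with the smallest p, and the 5 smallest adjusted p-values. Some genes that the rule chose are not reported here. Further genes were named after their values were seen, to describe lists and terms. KEGG and GO terms, taken from the annotation in the deposited count table, were tested after the results were seen, with a one-sided hypergeometric test against the tested genes that carry a term, for terms of 15 to 300 tested genes.

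The alternatives were RLE and upper quartile factors, library size only, no filter on low counts, a filter of 1 CPM in 3 libraries, DESeq2, limma-voom, a replicate block, stricter thresholds, each library left out in turn, camera with an estimated correlation, and fry. A correction for gene length and GC content, fitted with mgcv, was added after the data were examined. The edgeR test was tested on simulated data with 200 changed genes among 15670 tested genes, drawn from the means and library sizes of these libraries. For khellin against control it recovered 83.6% of genes raised and 83.0% of genes lowered 1.5-fold, and 96.1% and 89.4% of those changed 2-fold, and 10.7% of 197 calls fell on unchanged genes. The analysis used R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, mgcv 1.9.3, Python 3.11.15 and SciPy 1.17.1.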

Results

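RNA sequencing of polyadenylated RNA measured gene expression in MDA-MB-231 cells, a human triple-negative breast cancer line, with and without khellin, a furanochromone from the plant Ammi visnaga. The comparison had 3 control and 3 khellin libraries, and no dose or exposure time was given in the labels used here. The title of the series names DDIT4 and autophagy as its subject. The sample titles call 3 of the libraries control, whereas the design text of the series speaks of a docetaxel-resistant group. The labels thus do not settle whether the control cells were docetaxel-resistant. ABCB1, which encodes a drug efflux pump, had 0 or 1 read in each of the 6 libraries, under the floor of 3 counts that corresponds to 0.0969 to 0.105 CPM (counts scaled to library size). Total counts per library ranged from 28631578 to 30956610. A two-sided exact permutation test of the totals gave p = 0.3 (n = 3 per group), where 0.1 is the smallest value that 3 against 3 libraries allow. Mitochondrially encoded genes took 5.70 ± 0.268% of counts in control and 5.55 ± 0.178% in khellin libraries (exact permutation p = 0.4, n = 3 per group). Long noncoding genes took 1.24 ± 0.0318% in control and 1.18 ± 0.00880% in khellin libraries, without overlap between the groups (exact permutation p = 0.1, n = 3 per group). The first principal component of log2 CPM held 49.1% of the variance and separated the khellin from the control libraries, and the second held 19.9%.

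DDIT4, the gene in the title of the series and an inhibitor of the kinase complex mTORC1, rose with khellin in 3 of 3 libraries. The gene (ENSG00000168209) lies on the plus strand of chromosome 10 from 72273919 to 72276036 and went from 75.05 ± 7.88 CPM (SD, n = 3) in control to 169.6 ± 9.19 CPM (SD, n = 3) in khellin libraries. Its log2 fold change was 1.18 (SE 0.0761), a 2.26-fold rise, with an adjusted p of 2.0e-05 from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. DDIT4L, the paralogue of DDIT4, was measured at far lower levels, 1.78 ± 0.358 CPM in control and 0.925 ± 0.175 CPM in khellin libraries, and fell by 0.94 on the log2 scale (SE 0.211, edgeR adjusted p = 0.013). This call on DDIT4L, which was chosen after its values were seen, was lost without khellin replicate 1 (edgeR adjusted p = 0.0587).

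**Figure D1:**
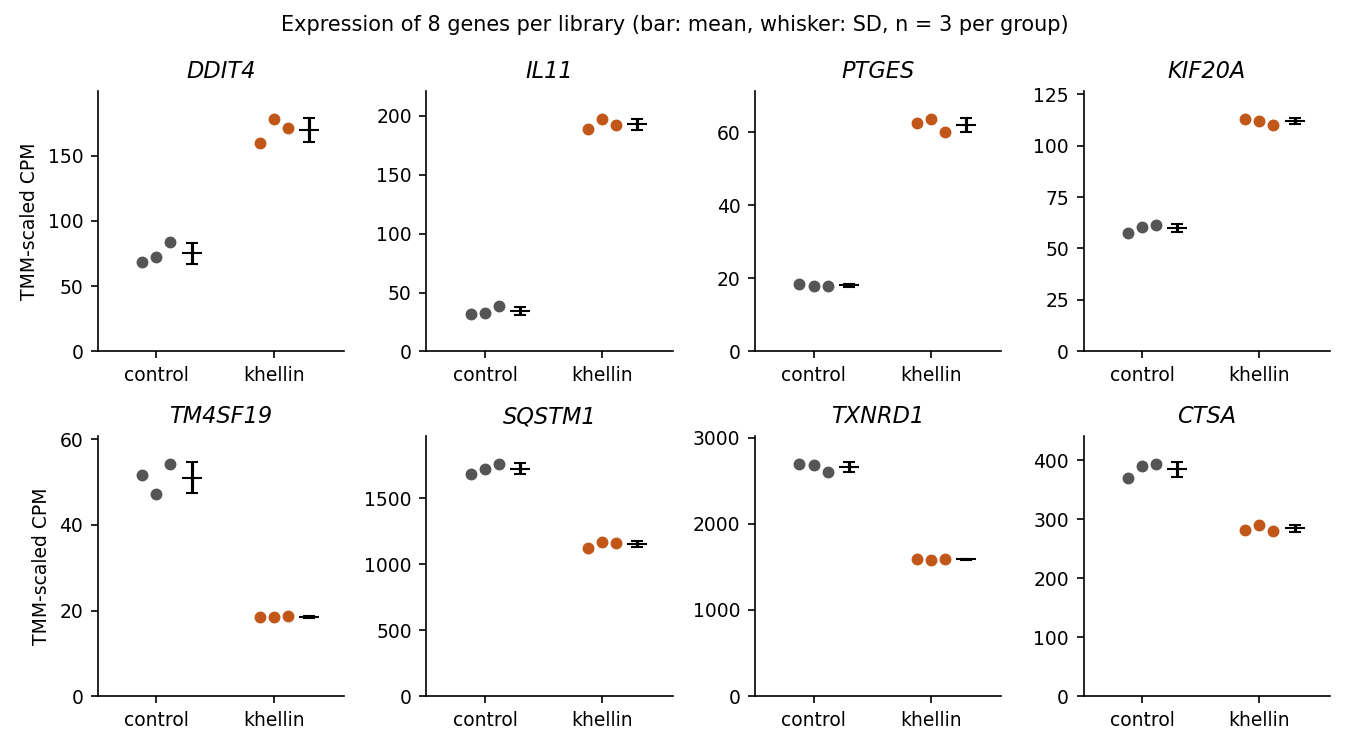
TMM-scaled CPM of 8 genes in each control (grey) and khellin (orange) library, with the mean and SD of the 3 libraries beside the points and axes that start at 0. DDIT4, IL11, PTGES and KIF20A were higher in every khellin library than in every control library, and TM4SF19, SQSTM1, TXNRD1 and CTSA were lower in every khellin library.

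Of 15865 genes tested, 1681 were higher and 1399 lower in khellin libraries at an adjusted p under 0.05 in edgeR's quasi-likelihood test, and 174 of the higher and 57 of the lower ones changed at least 2-fold. The median absolute log2 fold change of the called genes was 0.35. The 6 libraries separated by group without overlap for 38.2% of tested genes, where chance gives 10%. Scaling by library size alone gave 2208 higher and 986 lower genes, so that 69.1% of calls were higher against 54.6% as reported. The balance turned the other way with DESeq2, which gave 1344 higher and 1418 lower genes, and with the length and GC correction, which gave 2499 and 2653. With 1 library left out the counts moved by over 1.5 times, to 978 higher and 769 lower without control replicate 2, to 960 and 691 without khellin replicate 1, to 1073 and 836 without khellin replicate 2, and to 919 and 643 without khellin replicate 3.

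The largest rise was that of IL11, a cytokine of the interleukin 6 family, from 34.3 ± 3.43 to 192.8 ± 4.45 CPM (SD, n = 3 per group). This gene (ENSG00000095752, minus strand of chromosome 19, 55364382 to 55370463) had a log2 fold change of 2.49 (SE 0.0700) and the smallest adjusted p of the table, 3.3e-07 in edgeR's quasi-likelihood test. CSGALNACT1, a glycosyltransferase of chondroitin sulfate synthesis on chromosome 8 (19404161 to 19758029), followed with a log2 fold change of 2.05 (SE 0.0771), from 3.67 ± 0.108 to 15.2 ± 0.183 CPM. The transcription factor gene ATOH8 rose by 1.98 (SE 0.110) and ASB2, which encodes a substrate adaptor of a ubiquitin ligase, by 1.79 (SE 0.0943). PTGES, the inducible prostaglandin E synthase (chromosome 9, 129738331 to 129753042), rose from 18.1 ± 0.377 to 62.0 ± 1.92 CPM, a log2 fold change of 1.78 (SE 0.0580). The integrin gene ITGA10, the nicotinamide methyltransferase gene NNMT, MISP, DMBT1 and OLFML2A completed the 10 largest rises among genes of at least 5 CPM, with log2 fold changes of 1.62, 1.58, 1.54, 1.47 and 1.45. FOSL2, a subunit of the AP-1 transcription factor, was among the 5 genes with the smallest adjusted p (1.0e-06 in edgeR's quasi-likelihood test) and rose from 113.2 ± 2.28 to 242.0 ± 2.99 CPM, a log2 fold change of 1.10 (SE 0.0410).

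The largest fall was that of TM4SF19, a tetraspan membrane protein gene, from 51.0 ± 3.61 to 18.5 ± 0.201 CPM (log2 fold change -1.46, SE 0.0684, n = 3 per group). HKDC1, a hexokinase gene, fell by 1.43 (SE 0.0655) and SUN3 by 1.31 (SE 0.0973). The keratin gene KRT15 had a log2 fold change of -1.17 (SE 0.118), and the noncoding RNA genes NAV2-AS6, LUCAT1, TM4SF19-AS1 and LNCOG had values of -1.16, -1.10, -1.07 and -1.05. AADACP1, a pseudogene with related copies nearby, stood at -1.20 (SE 0.150). TM4SF19 and TM4SF19-AS1 overlap on opposite strands, NAV2-AS6 lies opposite NAV2, and LUCAT1 lies opposite ADGRV1. Since the strand setting of the counting was not given in the sources used here, the counts of these and of other genes that overlap an annotated gene, 52 of the 111 chosen by the naming rule on the opposite and 12 on the same strand, are uncertain as to which gene they belong to.

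The autophagy genes bear on the subject of the series, but their RNA levels do not measure autophagy itself. Of 41 autophagy machinery genes tested, 7 fell with khellin and 1 rose, and the other 33 did not pass the test, with the same counts adjusted over the list alone. For comparison, 3080 of all 15865 tested genes were called, 1399 lower and 1681 higher. EPG5 and VMP1, which act in autophagosome maturation and formation, fell by 0.53 (SE 0.0637) and 0.43 (SE 0.0393) on the log2 scale, ATG7 by 0.38 (SE 0.0594) and PLEKHM1 by 0.33 (SE 0.0506). MAP1LC3B, which encodes the LC3 protein of the autophagosome membrane, fell from 181.9 ± 6.04 to 157.2 ± 2.59 CPM (n = 3 per group), and its relative GABARAPL1 rose by 0.32 (SE 0.0608). PIK3C3 and BECN1, subunits of the phosphatidylinositol kinase that starts autophagosomes, fell by 0.24 and 0.19, while ULK1 stood at 0.09 and ATG5 at -0.07 without passing the test. Among 20 autophagy receptor genes SQSTM1, which encodes the receptor p62, fell from 1723 ± 40.6 to 1151 ± 22.4 CPM (log2 fold change -0.58, SE 0.0388), TOLLIP fell by 0.20 (SE 0.0513) and WDFY3 rose by 0.28 (SE 0.0602), with the same counts adjusted over the list alone. SQSTM1 also stands in the NRF2 list, so its fall is not separate from the fall of that list. The machinery list passed camera with a median of -0.05 (adjusted p = 0.0378, and adjusted p = 0.19 with an estimated correlation). Its median was 0.00 and no longer negative under scaling by library size alone, and the call was lost without control replicate 1 (adjusted p = 0.0615), without khellin replicate 1 (adjusted p = 0.0811) and with a replicate block (adjusted p = 0.0561). The receptor list did not pass (camera adjusted p = 0.0951, median -0.08). Calls on single genes were lost for PIK3C3 and BECN1 without control replicate 2, khellin replicate 2 or khellin replicate 3 (edgeR adjusted p of at most 0.0869) and for BECN1 also without khellin replicate 1 (0.0601). MAP1LC3B lost its call without khellin replicate 3 (edgeR adjusted p = 0.0565), and TOLLIP and WDFY3 theirs without control replicate 2, khellin replicate 1 or khellin replicate 3 (at most 0.105), TOLLIP also with library size alone (0.0512).

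Most lysosomal genes fell with khellin. Of 47 lysosome genes and targets of the transcription factor TFEB, 29 fell, 1 rose and 17 did not pass the test, and adjusted over the list alone 30 fell and 1 rose. CTSA, which encodes a lysosomal hydrolase, went from 384.9 ± 12.9 to 284.5 ± 5.88 CPM (n = 3 per group), a log2 fold change of -0.44 (SE 0.0425). CTSL, which encodes the protease cathepsin L, fell by 0.61 (SE 0.0669), ATP6V0A1, a proton pump subunit gene, by 0.40 (SE 0.0393) and LAMP1 by 0.27 (SE 0.0421), whereas NPC1, the cholesterol transporter gene, rose by 0.25 (SE 0.0419). TFEB itself stood at 0.12 (SE 0.0873, edgeR adjusted p = 0.36). The list passed camera (median -0.22, adjusted p = 1.4e-08, and adjusted p = 0.17 with an estimated correlation).

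Genes of the mTORC1 pathway and its inhibitors did not move as a list (median 0.01, camera adjusted p = 0.886). Computed from mean log2 CPM in place of the edgeR fit, the median was -0.01 with TMM and -0.02 with RLE factors but 0.04 with library size only. Of 29 tested, 3 rose and 3 fell, with the same counts adjusted over the list alone. Besides DDIT4, TXNIP rose by 0.30 (SE 0.0474) and DEPDC5 by 0.31 (SE 0.0765). DEPTOR, another inhibitor of the complex, fell by 0.60 (SE 0.113), DDIT4L by 0.94 and the Rag GTPase gene RRAGB by 0.23 (SE 0.0626). RRAGB lost its call without control replicate 2, khellin replicate 1, 2 or 3 (edgeR adjusted p of at most 0.129) and with library size alone (0.0650). DEPDC5 lost its call without the same libraries (at most 0.0889) and under DESeq2 (0.0561), and DDIT4L without khellin replicate 1 (0.0587). The median of this list was positive while the camera direction was negative.

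**Figure D2:**
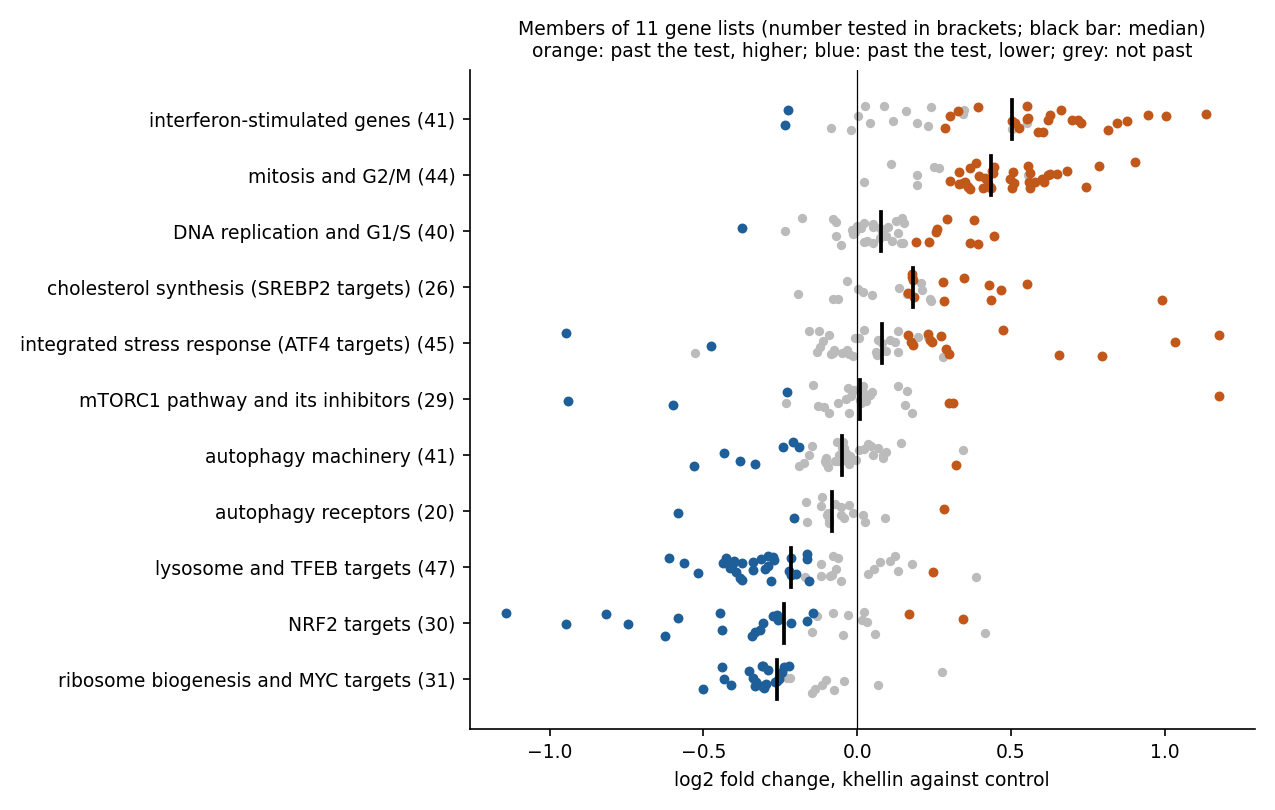
Log2 fold change of khellin against control (horizontal axis) for each tested member of 11 gene lists, with members past the test in orange (higher) or blue (lower), others in grey, and the median of each list as a black bar. Mitosis and interferon-stimulated genes lay mostly above 0, with medians of 0.44 and 0.50, and the lysosome, NRF2 and ribosome biogenesis lists mostly below 0, with medians of -0.22, -0.24 and -0.26.

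Mitotic genes rose together. Of 44 genes of mitosis and G2/M, 36 rose, none fell and 8 did not pass edgeR's quasi-likelihood test, and adjusted over the list alone 40 rose. KIF20A, a mitotic kinesin, went from 59.8 ± 1.99 to 111.8 ± 1.40 CPM (n = 3 per group), a log2 fold change of 0.90 (SE 0.0472). The mitotic kinase gene AURKA rose by 0.58 (SE 0.0389), the kinesin gene KIF2C by 0.55 (SE 0.0401), the cyclin gene CCNB1 by 0.56 (SE 0.0431) and MKI67, a marker of proliferating cells, by 0.51 (SE 0.0572). The list had a median of 0.44 and passed camera (adjusted p = 3.8e-18, and adjusted p = 0.0139 with an estimated correlation). Of 40 genes of DNA replication and G1/S, 9 rose and 1 fell, 11 and 1 when adjusted over the list alone. LIG1, E2F8 and GINS4 rose by 0.39 (SE 0.0520), 0.38 (SE 0.0603) and 0.37 (SE 0.0593), and the cyclin gene CCNE1 fell by 0.37 (SE 0.0749), a call lost without khellin replicate 3 (edgeR adjusted p = 0.0509). That list had a median of 0.08 and passed camera with an adjusted p of 0.013 (adjusted p = 0.19 with an estimated correlation). None of 10 tested replication-dependent histone genes passed edgeR's quasi-likelihood test, adjusted over all genes or adjusted over the list alone (list median -0.04 but above 0 with library size only, camera adjusted p = 0.622). H2BC12, H1-2 and H4C8, with the smallest p of them, stood at -0.17 (SE 0.0711), -0.15 (SE 0.131) and -0.14 (SE 0.135).

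Interferon-stimulated genes rose with khellin. Of 41 tested, 24 rose, 2 fell and 15 did not pass the test, and adjusted over the list alone 29 rose and 2 fell. IFIT2 and IFIT1, which encode antiviral RNA-binding proteins, went from 307.3 ± 6.64 to 486.7 ± 5.31 CPM and from 169.3 ± 4.77 to 297.8 ± 14.3 CPM (n = 3 per group), log2 fold changes of 0.66 (SE 0.0388) and 0.81 (SE 0.0486). OASL rose from 68.1 ± 3.84 to 136 ± 7.60 CPM. PARP12 fell by 0.23 (SE 0.0649), a call that was lost without control replicate 2, khellin replicate 1 or khellin replicate 3 (edgeR adjusted p of at most 0.138) and with library size alone (0.0724). The list had a median of 0.50 and passed camera (adjusted p = 5.2e-11, and adjusted p = 0.0207 with an estimated correlation). Among 21 antigen presentation genes, 7 rose and 2 fell (7 and 3 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.0648). CIITA, the activator of class II genes, rose from 4.20 ± 0.430 to 8.87 ± 0.310 CPM, HLA-DRA by 1.23 (SE 0.0749) and CD74 by 0.58 (SE 0.0653). CALR and TAP2 fell by 0.20 and 0.18, and both lost the call without control replicate 2, khellin replicate 1 or khellin replicate 3 (edgeR adjusted p of at most 0.117) and with library size alone (at most 0.0984). TAP2 also lost it without control replicate 1 (0.0729) and khellin replicate 2 (0.146).

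Inflammatory and immediate early genes went both ways. Of 30 NF-kB targets and cytokines, 12 rose and 7 fell, 12 and 9 when adjusted over the list alone, and the list did not pass camera (median 0.06, adjusted p = 0.34). Besides IL11, the cytokine genes IL1B and IL6 rose from 35.9 ± 1.77 to 71.8 ± 0.650 CPM and from 25.9 ± 0.756 to 51.3 ± 0.419 CPM (n = 3 per group). CSF3, the gene of a granulocyte growth factor, rose by 1.10 (SE 0.0673). PTX3, which encodes a secreted pattern recognition protein, fell by 0.67 (SE 0.0468). Of 34 immediate early genes, 13 rose and 4 fell, 13 and 5 when adjusted over the list alone. The phosphatase genes DUSP4 and DUSP1 rose by 0.65 (SE 0.0404) and 0.86 (SE 0.0570), and the 4 that fell were MYC by 0.41 (SE 0.0442), DUSP5 by 0.30, FOSL1 by 0.28 and JUN by 0.23, the last lost without control replicate 2, khellin replicate 1 or khellin replicate 3 (edgeR adjusted p of at most 0.0699). That list passed camera with a median of 0.11 (adjusted p = 0.012, and adjusted p = 0.19 with an estimated correlation).

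Targets of the antioxidant transcription factor NRF2 fell. Of 30 tested, 18 fell, 2 rose and 10 did not pass the test, and adjusted over the list alone 19 fell and 2 rose. SQSTM1, described above among the autophagy receptors, is 1 of the 18 that fell. TXNRD1, which encodes thioredoxin reductase (chromosome 12, 104215779 to 104350307), fell from 2660 ± 52.5 to 1587 ± 8.46 CPM (n = 3 per group), a log2 fold change of -0.74 (SE 0.0366). OSGIN1 fell by 0.82 (SE 0.0689) and the ferritin light chain gene FTL by 0.63 (SE 0.0744). ABCC3, a transporter gene, rose by 0.34 (SE 0.0642). The list passed camera (median -0.24, adjusted p = 4.5e-06, and adjusted p = 0.19 with an estimated correlation). Of 24 genes of ferroptosis and iron, 2 rose and 4 fell (2 and 5 adjusted over the list alone), HMOX1, the haem oxygenase gene, by 0.95 (SE 0.0862) and the ferritin heavy chain gene FTH1 by 0.33 (SE 0.0418), and the list did not pass camera (median -0.06, adjusted p = 0.34). SAT1, a polyamine catabolism gene, rose by 0.49 (SE 0.0541), PTGS2 by 0.47 (SE 0.121), and CISD1 fell by 0.25 (SE 0.0638). PTGS2 lost its call without any of control replicates 2 and 3 and khellin replicates 1 and 3 (edgeR adjusted p of at most 0.138) and with no filter on low counts (0.161). CISD1 lost its call without control replicate 2, khellin replicate 1 or khellin replicate 2 (at most 0.1004) and with the length and GC correction (0.324).

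Of 45 target genes of the integrated stress response, 14 rose and 2 fell, 15 and 2 when adjusted over the list alone. DDIT4 is 1 of them, the amino acid transporter gene SLC6A9 rose by 0.66 (SE 0.0673), the stress cytokine gene GDF15 by 0.80 (SE 0.0908) and STC2 by 1.03 (SE 0.167). HMOX1 fell from 44.7 ± 5.23 to 23.2 ± 0.857 CPM (n = 3 per group) and PPP1R15A, which encodes a phosphatase subunit that ends the response, fell by 0.48 (SE 0.0511), while DDIT3, which encodes the factor CHOP, stood at -0.16 (SE 0.0700, edgeR adjusted p = 0.152). The list had a median of 0.08 and passed camera with an adjusted p of 0.0385 (adjusted p = 0.511 with an estimated correlation), and the call was lost without control replicate 1 (0.0998), control replicate 2 (0.0786) or khellin replicate 2 (0.0740), with a replicate block (0.0631) and with the length and GC correction (0.0956). Of 35 genes of endoplasmic reticulum chaperones and degradation, 3 rose and 6 fell, also adjusted over the list alone, and the list did not pass (median -0.02 but 0.03 with library size only, camera adjusted p = 0.34). The 3 that rose were XBP1 by 0.28 (SE 0.0436), SEC24D by 0.26 (SE 0.0498) and HERPUD1 by 0.21 (SE 0.0412). Of 23 heat shock genes 3 fell, also adjusted over the list alone, namely HSPA8 by 0.37 (SE 0.0350), HSP90AB1 by 0.21 (SE 0.0356) and DNAJB6 by 0.19 (SE 0.0489). That list passed camera with a median of -0.10 (adjusted p = 0.0163, and adjusted p = 0.211 with an estimated correlation), a call lost without control replicate 3 (0.0687), and DNAJB6 lost its call without any single khellin replicate (edgeR adjusted p of at most 0.103) and with library size alone (0.0552).

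Cholesterol synthesis genes rose. Of 26 SREBP2 targets tested, 13 rose, none fell and 13 did not pass edgeR's quasi-likelihood test, and adjusted over the list alone 16 rose. HMGCS1, which encodes an early enzyme of the pathway, went from 92.3 ± 5.01 to 136 ± 6.14 CPM (n = 3 per group), a log2 fold change of 0.55 (SE 0.0558), and HSD17B7, a later enzyme of the pathway, rose by 0.47 (SE 0.0594). The list passed camera (median 0.18, adjusted p = 9.8e-05, and adjusted p = 0.0753 with an estimated correlation). Of 16 fatty acid synthesis genes, 7 rose and 1 fell, 8 and 2 when adjusted over the list alone. FASN rose by 0.30 (SE 0.0433), ACSS2 by 0.34 (SE 0.0536) and FADS2 by 0.25 (SE 0.0442), and the malic enzyme gene ME1 fell by 0.26 (SE 0.0685), a call lost without control replicate 2, khellin replicate 2 or khellin replicate 3 (edgeR adjusted p of at most 0.0983) and with library size alone (0.0519). This list passed camera with a median of 0.12 (adjusted p = 0.0378, and adjusted p = 0.19 with an estimated correlation), a call lost without control replicate 2 (0.0655), control replicate 3 (0.132), khellin replicate 2 (0.0509) or khellin replicate 3 (0.0551), with a replicate block (0.0613) and with the length and GC correction (0.0995). Glycolysis genes went both ways, with 5 of 21 higher and 4 lower (5 and 5 adjusted over the list alone), the hexokinase genes HK1 and HK2 down by 0.37 (SE 0.0437) and 0.49 (SE 0.0466) and the glucose transporter gene SLC2A1 up by 0.25 (SE 0.0469). Of 31 hypoxia targets, 8 rose and 3 fell (9 and 4 adjusted over the list alone), ANGPTL4, a lipase inhibitor gene, by 0.94 (SE 0.0688), HK2 and ENO2, the last by 0.25 and lost without khellin replicate 1 or 3 (edgeR adjusted p of at most 0.0542). Neither the glycolysis (median 0.01 but below 0 with RLE factors, camera adjusted p = 0.647) nor the hypoxia list (0.191) passed. The glycolysis median was positive while its mean of -0.01 and the camera direction were negative.

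Ribosome biogenesis genes and MYC targets fell. Of 31 tested, 21 fell, none rose and 10 did not pass edgeR's quasi-likelihood test, and adjusted over the list alone 23 fell. MYC went from 263.3 ± 9.51 to 198.0 ± 4.40 CPM (n = 3 per group), and RRP12 and RRS1, factors of ribosome assembly, fell by 0.44 (SE 0.0480) and 0.50 (SE 0.0645). The list passed camera (median -0.26, adjusted p = 5.6e-10, and adjusted p = 0.0753 with an estimated correlation). The 78 ribosomal protein genes themselves differed little, with a median of -0.10, and none passed adjusted over the list alone. RPL23 at -0.25 (SE 0.0699, edgeR adjusted p = 0.0338) was the 1 member past the test over all genes. RPL10A, next by p, stood at -0.27 (SE 0.0808, edgeR adjusted p = 0.0515) and RPL9 at -0.18 (SE 0.0629). Their share of counts was 3.26% in control replicate 3 and between 2.61 and 2.88% in the other 5 libraries. The list passed camera (adjusted p = 0.00771, and adjusted p = 0.714 with an estimated correlation), but without control replicate 3 the median was 0.03 and the adjusted p 0.593, and with the length and GC correction the adjusted p was 0.122. With fry, which tests a list against no change and not against the other genes, it was 0.537. Of 55 nuclear-encoded genes of oxidative phosphorylation 1 fell, SDHC by 0.21 (SE 0.0528), and none passed adjusted over the list alone. The ATP synthase genes ATP5PB and ATP5F1C stood at -0.16 (SE 0.0505) and -0.12 (SE 0.0451) without passing the test. That list passed camera with a median of -0.12 (adjusted p = 0.0133, and adjusted p = 0.683 with an estimated correlation), a call lost without control replicate 3 (0.711), with fry (0.466) and with the length and GC correction (0.246). The 13 mitochondrially encoded genes did not pass as a list (median -0.10, camera adjusted p = 0.0797), and none of them passed adjusted over the list alone. MT-CO1 was the 1 member past the test over all genes, at -0.14 (SE 0.0409), while MT-CYB and MT-ND6 stood at 0.13 (SE 0.0453) and -0.28 (SE 0.0979). RPL23, SDHC and MT-CO1 lost their calls without khellin replicate 1 or 3, RPL23 and MT-CO1 without control replicate 2, and RPL23 and SDHC without khellin replicate 2 (edgeR adjusted p of at most 0.153 for each). RPL23 and MT-CO1 also lost theirs with library size alone (0.0589 and 0.127) and with the length and GC correction (0.0504 and 0.0598 from edgeR), MT-CO1 also with upper quartile factors (0.0955) and a replicate block (0.0571).

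Most tested markers of luminal breast cells rose with khellin, and most epithelial genes did not pass the test. Of 15 luminal markers tested, 9 rose and none fell in edgeR's quasi-likelihood test, also adjusted over the list alone, with AGR2 going from 1.76 ± 0.348 to 4.62 ± 0.0523 CPM (n = 3 per group) and ERBB3 up by 0.73 (SE 0.0944). ESR1, the oestrogen receptor gene, stayed near the floor, at 0.280 ± 0.104 and 0.322 ± 0.109 CPM, and GATA3 stood at 0.11 (SE 0.0844). Of 17 epithelial genes, 5 rose, none fell and 12 did not pass the test, 6 and none adjusted over the list alone, with the keratin genes KRT7 up by 1.09 (SE 0.0633) and KRT8 by 0.32 (SE 0.0467), SPINT1 by 1.06 (SE 0.1197) and CLDN7 by 0.51 (SE 0.0980). ELF3, the remaining 1 of the 5, was at 0.326 ± 0.220 and 1.15 ± 0.351 CPM and lost its call without khellin replicate 3 (edgeR adjusted p = 0.0602), and EPCAM stood at -0.15 (SE 0.133). The luminal list passed camera with a median of 0.21 (adjusted p = 8.4e-05, and adjusted p = 0.17 with an estimated correlation) and the epithelial list with a median of 0.10 (adjusted p = 0.0163, and adjusted p = 0.19 with an estimated correlation), the latter lost without control replicate 1 (0.0588). Of 5 tested markers of fibroblasts and endothelial cells 3 rose, also adjusted over the list alone, COL1A1 by 0.86 (SE 0.0793), PDGFRB by 1.35 (SE 0.371) and PECAM1 by 0.62 (SE 0.158), with PDGFRB at 0.371 ± 0.191 and 0.945 ± 0.276 CPM. This list passed camera (median 0.62, adjusted p = 0.0257, and adjusted p = 0.19 with an estimated correlation), a call lost without control replicate 3 (0.0895) and with the length and GC correction (0.0808). PDGFRB lost its call without control replicate 3, khellin replicate 2 or khellin replicate 3 (edgeR adjusted p of at most 0.132) and with a replicate block (0.0526). PECAM1 lost its call without control replicate 2, khellin replicate 1 or khellin replicate 2 (at most 0.0786) and under DESeq2 (0.0545). Markers of blood cells were too few among the tested genes for a list test.

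Mesenchymal genes and targets of TGF-beta and YAP went both ways. Of 25 mesenchymal genes, 9 rose and 3 fell, 11 and 3 when adjusted over the list alone. The collagen gene COL5A1 rose from 60.7 ± 1.55 to 93.7 ± 1.09 CPM (n = 3 per group) and the fibronectin gene FN1 by 0.63 (SE 0.0596), CD44 fell by 0.29 (SE 0.0391), and the vimentin gene VIM stood at 0.12 (SE 0.0423, edgeR adjusted p = 0.0723). ITGA5 fell by 0.16 (SE 0.0478), a call lost without control replicate 2, khellin replicate 1 or khellin replicate 3 (edgeR adjusted p of at most 0.183), with library size alone (0.119), upper quartile factors (0.0780) and a replicate block (0.0559). The mesenchymal list did not pass (median 0.12, camera adjusted p = 0.0626). Of 21 TGF-beta targets, 8 rose and 2 fell (11 and 2 adjusted over the list alone), with ID1 up by 0.88 (SE 0.0566) and PMEPA1 by 0.79 (SE 0.0713), and CCN2 down by 0.39 (SE 0.0391). This list passed camera with a median of 0.27 (adjusted p = 0.0133, and adjusted p = 0.19 with an estimated correlation). Of 24 YAP targets, 4 rose and 7 fell (5 and 8 adjusted over the list alone), with ANKRD1 from 1917 ± 28.5 to 940.0 ± 62.1 CPM, and the list did not pass (median 0.01 but below 0 with RLE factors, camera adjusted p = 0.442). Its median was positive while its mean of -0.05 and the camera direction were negative.

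The remaining lists did not pass camera. Of 29 p53 targets, 4 rose and 6 fell, also adjusted over the list alone, with DDB2 up by 0.79 (SE 0.0694), GADD45A and PLK2 down by 0.67 (SE 0.0608) and 0.41 (SE 0.0402), and the cell cycle inhibitor gene CDKN1A down by 0.34 (SE 0.0546) (list median 0.02, adjusted p = 0.542). Of 34 apoptosis genes, 5 rose and 4 fell (6 and 5 adjusted over the list alone), with BIRC5 up by 0.39 (SE 0.0530), the anti-apoptotic gene BCL2L1 down by 0.36 (SE 0.0579), and APAF1 up by 0.42 (SE 0.0972) but lost without khellin replicate 1 (0.0588) or khellin replicate 3 (0.0727; list median 0.02, camera adjusted p = 0.970). The p53 and apoptosis lists had positive medians and means while the camera direction was negative. Of 26 efflux pump and tubulin genes related to taxanes, 1 rose and 4 fell, also adjusted over the list alone. ABCC3 rose by 0.34 (SE 0.0642), the tubulin gene TUBB6 fell from 593.2 ± 47.7 to 398.7 ± 13.3 CPM (n = 3 per group), CLU by 0.54 (SE 0.0556), and the pump genes ABCG2 and ABCC4 fell by 0.66 (SE 0.152) and 0.26 (SE 0.0681). ABCG2 lost its call without khellin replicate 1 or 3 (edgeR adjusted p of at most 0.0637), and ABCC4 without control replicate 2 or any single khellin replicate (at most 0.107) and with library size alone (0.0578). The list had a median of -0.02 but 0.03 with library size only, and a camera adjusted p of 0.189. Of 15 targets of the aryl hydrocarbon receptor, 6 rose and 2 fell (6 and 3 adjusted over the list alone), with ALDH3A1 up from 3.09 ± 0.264 to 6.19 ± 0.258 CPM, SERPINB2 down by 0.74 (SE 0.0435) and CYP1A1 at 0.14 (SE 0.0816, edgeR adjusted p = 0.274). TIPARP fell by 0.24 (SE 0.0613), a call lost without control replicate 2 or any single khellin replicate (edgeR adjusted p of at most 0.0996) and with library size alone (0.0536). The list had a camera adjusted p of 0.0978.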

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

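Of the 102 called genes chosen by the rule, 93 kept direction and call under all 15 alternatives and none reversed, and DDIT4 ranged from 1.115 to 1.262. Of the 62 genes named after their values were seen, 53 were called, 33 of these kept the call under all alternatives, 20 lost it under at least 1 and none reversed. Counts higher and lower were 174 and 57 at 2-fold or more, 808 and 608 at an adjusted p under 0.01, both stricter by construction, and 2499 and 2653 with the length and GC correction, where the cause was not tested. Without 1 library they ranged from 919 to 1990 and from 643 to 1722, higher than reported without control replicate 1 or 3 and lower without any other library, and 14 to 18 lists passed, where the cause was not tested. Lists past the test were 18 with RLE factors, 17 with the CPM filter, 15 with the replicate block, 24 with fry, which tests against no change and not against the other genes and lost the ribosomal protein and oxidative phosphorylation lists, 13 with the length and GC correction and 2 with an estimated correlation. The block gave 1533 higher and 1282 lower genes and cost the autophagy machinery, integrated stress response and fatty acid lists and the genes MT-CO1, PDGFRB and ITGA5 their calls. Deviations of same-number libraries correlated at 0.14, 0.03 and -0.12, and not every library correlated best with its own number (control replicate 3 with khellin replicate 2, 0.21). Some lists not past the test turned in tested direction, for which the cause was not tested. For mTORC1 (median 0.0109) and apoptosis (0.0159) fry gave the higher and camera the lower direction with the same medians. With the length and GC correction the direction turned for histones, whose median became 0.0385, and for mitochondrially encoded genes, whose median stayed negative at -0.0172. Without 1 library medians ranged from -0.0213 to 0.0246 (mTORC1), -0.0116 to 0.0406 (glycolysis), -0.0790 to -0.0129 (histones), and -0.00089 to 0.0349 (apoptosis). The ribosomal protein list, which passed as reported, ranged from -0.172 to 0.0329 and turned without control replicate 3, where the cause was not tested. Genes not past the test also turned: without 1 library ATG5 stood at -0.122 to 0.00701 and ESR1 at -0.0498 to 0.462. Length and GC were known for 15299 genes. Across those of them with a mean log2 CPM above 2, log2 fold change had a Spearman rho of 0.179 with length and 0.056 with GC. Depth limits genes near 3 counts per library, such as ABCB1.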

Other observations

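The gene annotation terms in this part were tested, and the genes of these terms named, only after the results of the comparison were seen. The hypergeometric test treats genes as independent. Its p-values do not measure the spread between libraries and can be too small where genes move together. Collagen and matrix genes were among the genes that rose with khellin, as were 3 of 5 markers of fibroblasts and endothelial cells (COL1A1, PDGFRB and PECAM1), of which COL1A1 is also a collagen term member. Of 105 tested genes of the extracellular matrix term, 33 were higher, against 12.4 by chance (one-sided hypergeometric test, adjusted p = 9.6e-05). COL7A1, whose product anchors epithelia to the tissue below, went from 19.9 ± 0.199 to 44.2 ± 0.702 CPM (SD, n = 3 per group), and COL4A5, a basement membrane collagen gene, rose by 0.77 on the log2 scale (SE 0.0799). COL17A1, a collagen gene of hemidesmosomes, fell by 0.97 (SE 0.0671). Of 26 tested genes annotated with the intermediate filament term, not all of them filament proteins, 11 rose (adjusted p = 0.00864 in the same test). Among them were KRT7, NES by 0.88 (SE 0.0775) and PPL by 0.83 (SE 0.125), while KRT15 and PNN fell, the latter by 0.21 (SE 0.0622). Of 33 genes of the kinesin complex 15 rose (adjusted p = 0.000491).

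Of 35 tested genes of the small-subunit processome, an assembly that makes the small ribosomal subunit, 18 fell (hypergeometric adjusted p = 4.7e-07), with NOL6 down by 0.46 (SE 0.0550) and WDR3 by 0.42 (SE 0.0522). Of 21 genes of rotary proton pumps 11 fell (adjusted p = 0.000274), with ATP6V0E1 and ATP6V1D, subunits of the pump that acidifies lysosomes, down by 0.43 (SE 0.0640) and 0.41 (SE 0.0475). The KEGG term for autophagy in animals held 20 lower genes of 120 and did not pass (hypergeometric adjusted p = 0.254), nor did that for mitophagy (0.684). The GO term for regulation of macroautophagy passed, with 12 lower genes of 34 (hypergeometric adjusted p = 0.00478). The KEGG lysosome term also passed, with 33 lower genes of 124 (8.5e-05 in the same test).

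The tests of length, scaling and admixture below were written before they were run, and the 2 tests on splits of the libraries were chosen only after the result was seen. The rise of mitosis and interferon-stimulated genes was weighed against gene length or GC bias and against library scaling. After the length and GC correction the smaller retained share of the 2 medians was 1.00021, which argues against length or GC bias. Over 3 other scalings it was 0.971. A change of scaling moves all genes by nearly the same amount. The median log2 fold change of all genes ran from -0.0105 with RLE factors to 0.0464 with library size only. Larger list medians must then keep most of their size. The scaling test thus shows only that the choice among these scalings does not account for the rise. The mean log2 CPM of mitosis genes minus that of G1/S genes was -0.243 ± 0.0593 in control and 0.126 ± 0.0457 in khellin libraries (n = 3 per group, exact permutation p = 0.1, the smallest possible). This comparison was not among the tests written beforehand. It is drawn from the same 2 lists, whose median log2 fold changes were 0.44 and 0.08, so it adds no separate evidence. A biological difference between the groups stays open, since no test here singles it out.

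The fall of lysosome, NRF2 and ribosome biogenesis genes was weighed against the same 2 explanations. The smallest retained share of the 3 medians was 0.856 after the length and GC correction, which argues against length or GC bias. It was 0.796 over 3 other scalings, which again shows only that the choice among these scalings does not account for the fall. A biological difference between the groups stays open here too.

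The rise of luminal and epithelial markers was weighed against gene length or GC bias, for which the smaller retained share was 0.884 and argues against it, and against cells of a luminal line mixed in. The summed CPM of 14 markers that control libraries hardly express went from 3.21 ± 0.295 to 4.78 ± 0.466 (n = 3 per group), a 1.49-fold rise (SE 0.115) so near the bound of 1.5 that the test cannot tell. With each marker left out in turn, a step added after the result was seen, the fold of this sum ranged from 1.25 without ELF3, which alone went from 0.322 to 1.16 CPM scaled by library size only, to 1.68 without CLDN3, on both sides of the bound. CDH1, left out of the sum because its counts had been seen, had 0 reads in each control library and 1, 2 and 2 in the khellin libraries, while GATA3 stood at 6.04 ± 0.240 and 6.52 ± 0.260 CPM and EPCAM at 4.53 ± 0.0845 and 4.09 ± 0.732 CPM, without passing the test. A biological difference between the groups stays open.

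Lists of 4 further regulators were written before they were tested, though after the other results were seen. Members in other lists are counted here only against the lists written before the data were examined. Targets of cAMP and CREB had 9 of 18 members higher and none lower (median 0.18, camera adjusted p = 0.000329, and adjusted p = 0.0606 with an estimated correlation), with PDE4B up by 1.82 (SE 0.189) and NR4A3 by 0.96 (SE 0.133), and 5 members stand in other lists. Retinoic acid targets had 4 of 8 higher (median 0.55, camera adjusted p = 0.000329, and adjusted p = 0.140 with an estimated correlation), with DHRS3 up by 1.20 (SE 0.154) and PLAAT4 by 1.16 (SE 0.114), and 1 member in another list. BMP targets had 5 of 14 higher and 1 lower (median 0.32, camera adjusted p = 0.0352, and adjusted p = 0.230 with an estimated correlation), with BMPER down by 0.59 (SE 0.110) and 6 members in other lists. Glucocorticoid receptor targets had 8 of 20 higher and 2 lower (median 0.02, camera adjusted p = 0.121, and adjusted p = 0.221 with an estimated correlation), with 3 members in other lists. In a test chosen only after these results were seen, the members shared with those earlier lists were left out. PER1, which is in both the cAMP and the glucocorticoid receptor list, stayed in both. The cAMP (camera adjusted p = 0.0188) and retinoic acid lists (0.00122) then still passed with the preset correlation, the BMP (0.696) and glucocorticoid receptor lists (0.544) did not, and none passed with an estimated correlation (lowest adjusted p = 0.193). The data may thus be in line with cAMP or retinoic acid signalling (0.000329 each over all members) only as far as camera with the preset correlation goes.

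The 6 libraries can be split into 3 and 3 in 10 ways. Of these splits 1, the real one, called 3080 genes, and the highest other split called 0. Likewise 1 split of 10, the real one, had 18 lists past the test, and each other split had from 5 to 10. Camera with the preset correlation thus passed lists in splits where no gene was called. With 10 splits the share cannot fall under 0.05. Each other split mixes libraries of both groups. Part of the difference between the groups then stays in the comparison, and part counts as spread. Neither the calls nor the lists of these splits therefore measure what chance alone gives.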
